A study of Homo sapiens with 29 samples.

How the data were processed

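The series holds 29 arrays, 1 for each of 29 established pancreatic cancer cell lines. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit and labelled with the Agilent Quick-Amp kit, the cell line in Cy5 and a pool of equal amounts of 30 pancreatic cancer cell lines in Cy3. All arrays had this dye orientation, with no dye swap. The titles name 2 preparations of the pool, mix B on 26 arrays and mix C on 3. Each line forms a group of its own with 1 array, so no comparison between replicated groups exists, and p-values measure the spread between lines.

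Per the file headers, the deposited scanner files hold spot intensity values in both channels, extracted with Agilent Feature Extraction 9.5.1.1 on the mix B arrays and 10.7.3.1 on the mix C arrays, while the submitters' processing notes name Agilent Feature Extraction 9.5.1. The headers name the hg17 build for the mix B arrays and hg19 for the mix C arrays. Positions are those of hg17. No annotation of that build was used here, so exons and untranslated regions are not stated. The scanner model also differs between the mixes. The median signals used here are raw: per the file headers and the columns, no background was subtracted before dye normalization. The log10 ratio column of the deposited files is Agilent's dye-normalized ratio of Cy5 over Cy3. The authors' value table holds the same log10 ratios: after conversion to log2, 99.7% of its cells agreed within 0.001 with that column, and the medians of its columns lay near 0. No column of per-sample values was left unused (0 columns).

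Median spot signals were background corrected with normexp in limma 3.58.1 (R 4.3.3), with the median local background and an offset of 50. They were then normalized within each array by loess, with control spots at weight 0 and outlier spots left out. Between 101 and 307 spots per array carried an outlier flag. Spots of one probe were averaged. The direction is log2 of line over pool, as the dyes in the labels give it. Agilent's own call of spots well above background was positive for 100% of spots, because no background had been subtracted, and had no use as a filter. In its place, a spot counted as well above background at 2 times the median negative control of its array, and a gene was kept when its line signal reached this on at least 1 array. This replaces the flag written in the design. A gene counted as above background in a line when any of its probes did, which need not be the probe used for its ratio. Median negative controls lay between 56 and 105.5 in Cy5 and between 42 and 69 in Cy3. Median probe signals lay between 308 and 669 in Cy5. Spots saturated in Cy5 numbered 0 to 23 per array and were kept.

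Of the 41000 probes, 23434 were named through their accession in a RefSeq gene table of the GRCh38.p14 assembly, 2317 through a current symbol and 1043 through an older symbol, and 14206 kept the name in the files. Gene names of the array design can be old. For a gene with several probes, the probe with the highest mean signal was used. Among 980 variable genes with a second probe (SD above 1), the 2 probes correlated over lines at a median r of 0.90, and 89 were below 0.5. Of the genes named in the text, CCNB2, MYC, CYP3A5 and LGR4 had such disagreement. Probes of genes on chromosome Y and of a fixed list of other sex-linked genes (104 in all) were left out, other genes of chromosome X were kept, and DAZL and the VCX genes, which have near-identical copies on a sex chromosome, were not named. The next gene of the same line took their place.

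Each line was set against the mean of the other 28 with limma's lmFit and eBayes, Benjamini-Hochberg adjusted over 26029 genes and 29 lines, and called at an adjusted p under 0.05 and a difference of at least 1 on the log2 scale. Slides with over 1 array were compared by limma's moderated F test, and mix C with mix B arrays by limma. Where a gene was not well above background on any array of one side, a fold is given as a lower bound. It sets the mean normalized line signal of the brighter side against that of the dimmer side, each array of the dimmer side taken at the higher of its background floor and the probe's own signal, and it is never set above the fold of the ratios. For the 2 PATU 8988 arrays, list medians were also taken with genes above background in 1 line at this bound and those in neither at 0. This limit, and these medians, were chosen after the data were seen. Such bounds are open to dye bias, as no dyes were swapped. The background floor of an array is the lowest normalized line signal among its probes counted above background. It can lie below the signal of a probe that is not so counted. This was so for PRR15L and ANXA10 in PATU 8988T, whose bounds are the plain fold of the ratios and of the line signals. The 25 gene lists and a list of 25 marker genes were written from general knowledge before the data were examined. List scores were related over lines by Pearson's r and Spearman's rho with two-sided permutation tests (100000 resamples, or all 720 orders for 6 lines). Where mclust 6.1.1 preferred 2 components by over 6 units of the Bayesian information criterion, correlations were computed within each set of lines. The plan named 13 pairs as the family, and as 4 pairs were split this way, 17 correlations were adjusted together. For the 2 PATU 8988 arrays, list medians were ranked among 10000 random lists of equal size and matched signal. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and statmod 1.5.0 in R, were used as well.

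The genes named were chosen by a rule written before the data were examined. It took the 20 genes of highest SD over lines and, for each line, the called gene with the largest positive difference. It also took the 5 calls with the largest negative difference, the 10 largest differences in each direction between PATU 8988S and PATU 8988T, 3 members of highest SD per list, and all marker genes. Not every gene that the rule gives is printed. Called members of lists, and members named for the PATU 8988 pair beyond this, were chosen after their values were seen. Alternatives fixed beforehand were Agilent's ratios, the authors' value table, a normexp offset of 10, median centring in place of loess, arrays scaled to equal spread, no filter, a filter on 3 arrays, the mean over probes, slide and mix as blocks or covariates, and leaving out the mix C arrays. Counting only calls also made on Agilent's ratios was added after the data were seen. The relation of calls to the spread of an array was also chosen after the data were seen.

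The limma fit was tested on simulated data, drawn from normal distributions independently for each gene and array. Real ratios need not follow these, so the counts below do not give the share of false calls in the real data. For 26029 simulated genes with the spreads of the real ones, of 50 genes shifted in a line by 2 on the log2 scale 42% were recovered, of 50 shifted by 3 46%, by 4 80% and by 6 92%, with 6 calls among unshifted genes. For the mix comparison, 79.5% of 200 genes shifted by 2 were recovered, with 16 calls among unshifted genes. For slides, 13% of 200 genes shifted on 1 slide by 3 times their SD were recovered, with 0 calls among unshifted genes, so that test has little power.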

Results

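RNA of 29 pancreatic cancer cell lines was measured on 2-colour Agilent arrays of 41000 probes, with each line (Cy5) hybridised against a pool of 30 pancreatic cancer lines (Cy3). The stated purpose of the series was to find expression specific to a line. There was 1 array per line, so no line has a replicate and the spread used throughout is that between lines. The pool was a preparation named mix B on 26 arrays and mix C on 3 arrays (Capan-1, HPAF-2 and CF PAC-1). Between 58.7% and 67.3% of the probes per array had a line signal at least 2 times the median negative control. After filtering, 26029 genes were analysed, of which 16342 carry a gene symbol. All values are log2 ratios of line over pool unless stated otherwise, and probe positions refer to the hg17 build named in the headers of the mix B arrays. The number of arrays limits the precision.

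The gene with the highest spread was CEACAM6, a cell surface glycoprotein of gut and pancreatic tumours (SD 3.35 over 29 lines, probe at chromosome 19, 46967609 to 46967668), which ranged from -7.07 in MIA PaCa-2 to 4.84 in HPAC. BNIP3, a mitochondrial protein induced by low oxygen (SD 3.3, chromosome 10, 133631301 to 133631360), was highest in CF PAC-1 (3.13) and well above background in only 19 lines, BxPC-3, where it was lowest, not among them. The annexin ANXA10 (SD 3.12), the amino acid transaminase BCAT1 (SD 3.12) and the lactate dehydrogenase subunit LDHB (SD 3.05) followed. LDHB ranged from -5.62 in Panc04.03 to 3.48 in SU.86.86. The membrane trafficking protein MAL2 (SD 3.03), BTBD6 (SD 2.99), HS6ST2 (SD 2.98), TM4SF4 (SD 2.96), keratin KRT23 (SD 2.90), the protease inhibitor TFPI2 (SD 2.89), AGR2 (SD 2.88) and the receptor ADGRF1 (SD 2.88) came next. The EGF receptor ligand EREG (SD 2.85), the sulfatase SULF2 (SD 2.83), CEMIP (SD 2.78), the collagenase MMP1 (SD 2.78), TSPAN8 (SD 2.75), the antimicrobial peptide DEFB1 (SD 2.69) and GNG11 (SD 2.63) completed the 20 genes of highest spread. For comparison, the Cy3 signal of the common pool had a median SD of 0.13 over the mix B arrays, against 0.52 for the Cy5 signal of the lines. Probes spotted 10 times on an array had a median SD of 0.05 between spots.

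Of 25 gene lists fixed before the data were examined, 13 held more members among the 5% most variable genes (1301 genes with an SD of at least 1.32) than chance gives. The test was Fisher's exact test, one-sided, with Benjamini-Hochberg adjustment over the lists. Genes are not independent replicates in such a test. The lists were set against all 26029 genes, of which 16342 carry a symbol, and were not matched on signal. How far signal contributes to an excess was not tested. The classical tumour subtype list had 19 of 25 measured members in the most variable set (adjusted p = 5.55e-19), with CEACAM6, ANXA10 and AGR2 in front. The basal-like list had 17 of 22 (adjusted p = 1.78e-17), led by SCEL (SD 2.47), FGFBP1 (SD 2.27) and the growth factor AREG (SD 2.25). The classical list of the 62-gene set had 12 of 20 members (adjusted p = 1.67e-10). These subtype lists come from earlier work on pancreatic tumours and lines, which can have included some of these lines, so they are not independent evidence. Mesenchymal genes had 12 of 22 (adjusted p = 5.87e-10), among them vimentin (VIM, SD 2.48), cadherin 11 (CDH11, SD 2.21) and LOXL2 (SD 2.17). Squamous keratinocyte genes had 8 of 19 (adjusted p = 7.32e-06), led by TP63 (SD 2.15), the regulator of stratified epithelium. MHC class II genes had 6 of 10 and interferon response genes 9 of 26 (adjusted p = 8.54e-06 each), with HLA-DPA1 (SD 1.86) and IFI27 (SD 1.83) the most variable. Cancer-testis antigens had 9 of 23 (adjusted p = 4.09e-06), epithelial junction genes 8 of 23 (adjusted p = 2.65e-05) and HOX genes 9 of 32 (adjusted p = 4.67e-05).

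NRF2 targets, which serve oxidative stress defence, had 6 of 19 members in the most variable set (adjusted p = 0.000541), with the aldo-keto reductases AKR1B10 (SD 2.0), AKR1C1 (SD 1.97) and AKR1C3 (SD 1.84) in front. Endoderm transcription factors had 5 of 18 (adjusted p = 0.0032), led by FOXA2 (SD 2.58), GATA6 (SD 1.93) and FOXA1 (SD 1.92). Quasi-mesenchymal genes of the 62-gene set had 5 of 20 (adjusted p = 0.00492), led by S100A2 (SD 1.86) and caveolin CAV1 (SD 1.84). The other lists did not pass. Exocrine-like genes had 3 of 15 members in the set, endocrine islet genes 3 of 17, mucins 2 of 11 and hypoxia and glycolysis genes 2 of 22. Cholesterol synthesis (1 of 20), liver and gut lipoprotein (1 of 16), fibroblast (1 of 12) and leukocyte (1 of 13) lists each had a single member. None of the 15 MHC class I, 26 proliferation, 42 ribosomal protein or 11 endothelial genes was in it. Their median SD per gene was 0.90, 0.82, 0.53 and 0.98.

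**Figure D1:**
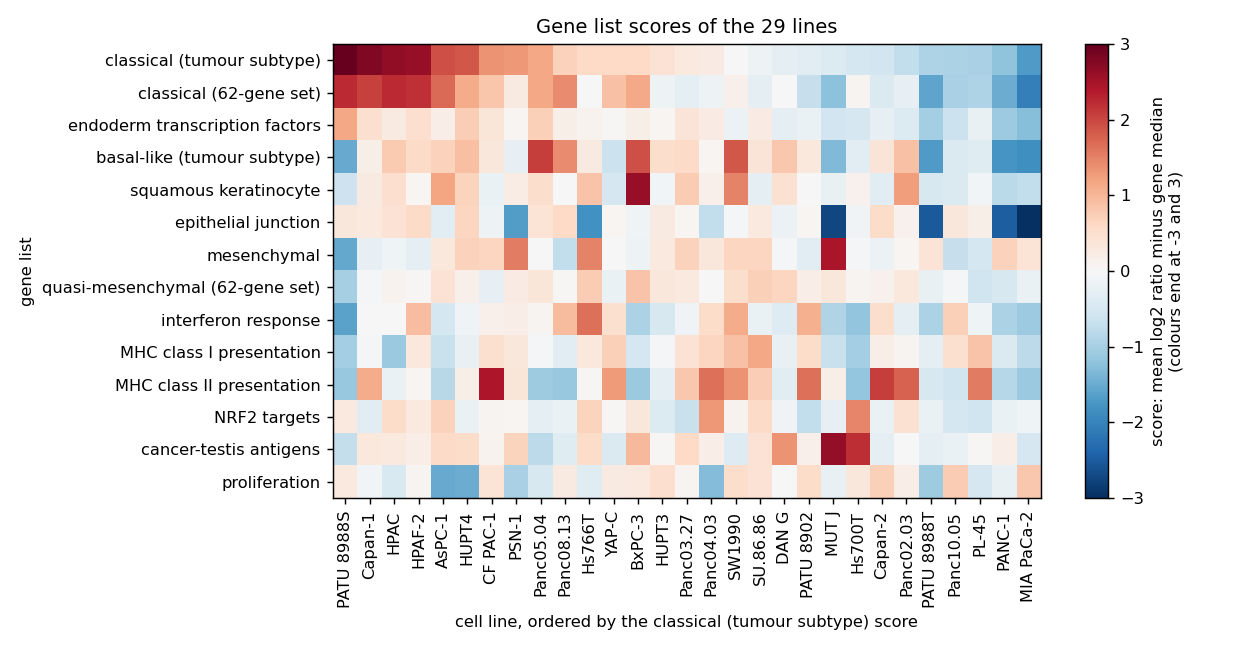
Scores of 14 gene lists (vertical) in the 29 lines (horizontal, ordered by the classical tumour subtype score); colour gives the mean log2 ratio of a list's genes after subtracting each gene's median over lines. PATU 8988S has the highest classical score (4.06), BxPC-3 the highest squamous score (2.60) and MUT J the highest cancer-testis score (2.64).

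Lines with more of the endoderm transcription factors had more of the classical subtype genes. A score was formed for each list and line as the mean over its genes after subtracting each gene's median over lines. The endoderm factor score correlated with the classical score at r = 0.85 and rho = 0.88 over 29 lines (two-sided permutation test, p = 1e-05 for both, the smallest that 100000 resamples can give, adjusted p = 5.67e-05 for r). Without MIA PaCa-2 and PANC-1, the lines farthest out in the factor score, r was 0.83. PATU 8988S had the highest scores in both lists (1.16 and 4.06), and MIA PaCa-2 the lowest (-1.27 and -1.69). With arrays scaled to equal spread, HUPT4 was highest and PATU 8988T lowest in the factor score, and MUT J lowest in the classical score. GATA6 was highest in PATU 8988S (2.19) and lowest in MIA PaCa-2, where it was not well above background, and FOXA2 ranged from -5.61 in PATU 8988T to 2.68 in DAN G. The classical lists of the tumour subtypes and of the 62-gene set, without shared genes, correlated at r = 0.78 and rho = 0.73 (n = 29, permutation p = 1e-05, the smallest possible, and 2e-05, adjusted p = 5.67e-05 for r), and at r = 0.75 without PATU 8988S and HPAF-2. Apart from the 5% farthest out, random list pairs gave r from -0.30 to 0.57 and from -0.36 to 0.50 over the lines, so chance lists reach well above 0, and both values lay above all 1000 pairs (percentile 100). With slide as a block, these coefficients were 0.87 and 0.75, and over the 26 mix B lines 0.85 and 0.73. Each slide holds at most 4 lines, too few for a correlation within a slide.

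Basal-like and squamous keratinocyte scores also rose together, at r = 0.75 and rho = 0.77 (n = 29, two-sided permutation p = 1e-05 for both, the smallest possible, adjusted p = 5.67e-05 for r). It lay at percentile 100 of the random list pairs. Without MIA PaCa-2 and PANC-1, r was 0.70, and with slide as a block 0.75. BxPC-3 had the highest squamous score (2.60), while Panc05.04 had the highest basal-like score (2.08). TP63 was highest in BxPC-3 (2.18) and lay at least 4-fold above its median in 7 lines. The classical and basal-like scores showed no inverse relation: r was 0.25 and rho 0.40 (n = 29, permutation p = 0.182 and 0.0322, adjusted p = 0.308 and 0.0783). Without PATU 8988S and Capan-1, the lines farthest out in the classical score, r was 0.53 (permutation p = 0.00399), so this coefficient depends on them. With slide as a block it was 0.20. GATA6, taken alone, correlated positively with the basal-like score (r = 0.52, rho = 0.45, n = 28, permutation p = 0.00456 and 0.0163, adjusted p = 0.0155 and 0.0463). This relation rested on MIA PaCa-2 and PANC-1, without which r was 0.22 (permutation p = 0.273), and with slide as a block it was 0.58. It also ended with arrays scaled to equal spread (r = 0.07). On Agilent's own ratios it was weaker and no longer passed (r = 0.42, permutation test, adjusted p = 0.0686). The classical and quasi-mesenchymal lists of the 62-gene set were not related (r = 0.03, rho = 0.10, n = 29, permutation p = 0.89 and 0.603, adjusted p = 0.89 for r, r = 0.26 without PATU 8988S and HPAC, -0.12 with slide as a block).

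**Figure D2:**
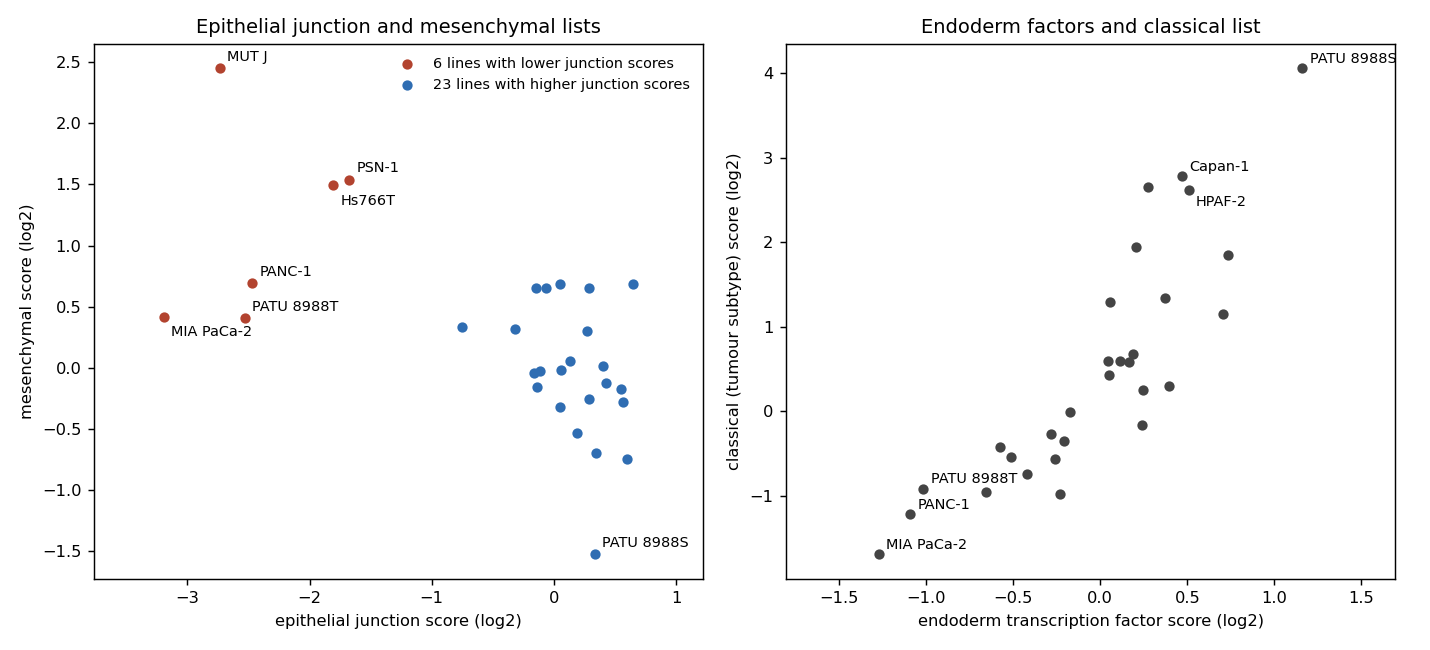
Left: epithelial junction score (horizontal, log2) against mesenchymal score (vertical, log2), 1 point per line, coloured by the split of 6 and 23 lines. Right: endoderm transcription factor score against classical score (log2), where r is 0.85 over the 29 lines.

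Epithelial junction genes separated the lines into a set of 6 with low scores (MIA PaCa-2, MUT J, PATU 8988T, PANC-1, Hs766T and PSN-1, from -3.19 to -1.67) and 23 with scores from -0.75 to 0.65. A mixture of 2 normal distributions was preferred over 1 by 25.9 units of the Bayesian information criterion, so correlations with this score were computed within each set. E-cadherin (CDH1), the main adhesion molecule of epithelium, lay at least 4-fold below its median in 6 lines and at -7.11 in MIA PaCa-2. EPCAM lay at -7.41 and MAL2 at -8.86 in that line. Vimentin, the intermediate filament of mesenchymal cells, ranged from -5.18 in Panc10.05 to 3.34 in MIA PaCa-2, and SPARC was highest in MUT J (3.56) and not well above background in PATU 8988S. MUT J had the highest mesenchymal score (2.45), and PATU 8988S the lowest (-1.53), or PATU 8902 with arrays scaled to equal spread. The 6 lines had mesenchymal scores from 0.41 to 2.45, and the 23 lines from -1.53 to 0.69. Correlations within each set leave out this difference between the sets, which was not tested. Within the 23 lines, junction and mesenchymal scores gave r = -0.32 and rho = -0.35 (permutation p = 0.132 and 0.104, adjusted p = 0.248 and 0.177), with r = -0.27 without Panc04.03 and AsPC-1 and -0.12 with slide as a block. Within the 6 lines, r was 0.33 and rho 0.31 (exact permutation p = 0.522 and 0.564, adjusted p = 0.592 and 0.631). It was 0.06 without PSN-1 and Hs766T.

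ZEB1, a repressor of epithelial genes, was lower where the junction score was higher in the 23 lines (r = -0.53, rho = -0.51, permutation p = 0.013 and 0.0147, adjusted p = 0.0369 and 0.0463, r = -0.50 without AsPC-1 and PATU 8988S). With slide as a block, r was -0.46 and no longer passed (adjusted p = 0.329, permutation test), and ZEB1 was above background in only 10 of the 29 lines. In the 6 lines, r was -0.73 and rho -0.77 (exact permutation p = 0.1 and 0.103, adjusted p = 0.213 and 0.177, r = -0.66 without MIA PaCa-2 and PANC-1). Junction and classical scores gave r = 0.25 and rho = 0.24 in the 23 lines (permutation p = 0.252 and 0.265, adjusted p = 0.329 and 0.376, r = 0.37 without Panc04.03 and AsPC-1, 0.25 with slide as a block). In the 6 lines they gave r = 0.91 and rho = 0.77 (exact permutation p = 0.0181 and 0.103, adjusted p = 0.0438 and 0.177). Apart from the 5% farthest out, pairs of random lists of these sizes and signals gave r from -0.60 to 0.92 in the 6 lines (percentile 97.4 for the real pair), so this value lies within what random lists give. The relation also rested on PSN-1 and Hs766T, without which r was 0.53 (exact permutation p = 0.5), and it turned to -0.32 with arrays scaled to equal spread. No slide block could be fitted within the 6 lines.

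Interferon response genes and MHC class I presentation genes rose and fell together over the lines. Their scores correlated at r = 0.65 and rho = 0.66 (n = 29, two-sided permutation p = 0.00015 and 0.00016, adjusted p = 0.000637 and 0.00068). It lay at percentile 99.5 of the random list pairs. Without Hs766T and PATU 8988S, r was 0.62, with slide as a block 0.67 and over the mix B lines 0.65. Hs766T had the highest interferon score (1.65) and PATU 8988S the lowest (-1.60), or MUT J with arrays scaled to equal spread. IFI44L ranged from -3.82 in MIA PaCa-2 to 2.33 in Hs766T, and HLA-C from -2.27 in PATU 8988S to 2.0 in SU.86.86. Hypoxia and cholesterol synthesis scores were not related (r = -0.08, rho = -0.09, n = 29, permutation p = 0.692 and 0.631, adjusted p = 0.735 for r, r = -0.16 without PATU 8988S and Panc05.04, 0.14 with slide as a block). NRF2 targets and proliferation gave r = -0.23 and rho = -0.16 (n = 29, permutation p = 0.226 and 0.416, adjusted p = 0.32 for r, r = -0.19 without Hs700T and Panc04.03, -0.23 with slide as a block). The tumour suppressor CDKN2A and its neighbour MTAP (chromosome 9, probes starting at 21958039 and 21827969) were lowest in the same line, MIA PaCa-2, at -3.3 and -2.99. That array had the widest spread of ratios (SD 1.05) and the most genes at least 4-fold below the pool (1644). A shared lowest line thus does not single out this pair. CDKN2A values fell into 15 lower and 14 higher lines. Within these, r with MTAP was 0.29 and 0.36 (permutation p = 0.302 and 0.2, adjusted p = 0.367 and 0.308), with rho of 0.37 and 0.27 (permutation p = 0.18 and 0.357). Without the farthest lines in MTAP, Panc08.13 and Panc03.27 in the first set and HPAF-2 and PATU 8988S in the second, r was 0.45 and -0.06. With slide as a block it was 0.62 and 0.55. As the sets were cut on CDKN2A itself, r within them leaves out any MTAP difference between the sets, which was not tested. In all, 17 correlations were adjusted together, and 7 had an adjusted p under 0.05.

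Of the other genes chosen as markers, SMAD4, a tumour suppressor of the TGF-beta pathway, was highest in PL-45 (1.22) and above background in 23 lines, Panc05.04, where it was lowest, not among them. ERBB2 ranged from -2.84 in SU.86.86 to 1.47 in Capan-1, and MYC from -1.72 in MUT J to 0.96 in HUPT3. Keratin KRT17 was highest in BxPC-3 (2.19), KRT81 in Panc05.04 (2.27) and KRT7 in HUPT4 (1.56). The surface antigens MSLN (1.96) and MUC1 (1.89) and the secreted trefoil peptide TFF1 (2.02) were highest in HPAC, and MUC16 in SW1990 (1.99). HNF4A (SD 0.15) and CYP3A5 (SD 0.21) varied little in these ratios, and HNF4A was above background in 3 lines. Second probes of CYP3A5 and MYC did not follow the first over lines (r = -0.28 and -0.17), so their values hold for the probe used only. The receptor kinase AXL was lowest in Hs700T (-4.62), and SOX9 in PATU 8988T (-3.20).

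The question of expression specific to a line was tested by setting each line against the other 28 with limma, with Benjamini-Hochberg adjustment over all genes and lines. At an adjusted p under 0.05 and a difference of at least 1 on the log2 scale, there were 2560 calls, 2335 of them higher and 225 lower in the line. They covered 2545 genes, 2530 of them called in a single line and 15 in 2 lines. The other 28 lines give the spread, so a gene high in several lines is hard to call. CEACAM6, at least 4-fold above its median in 12 lines, was not called in any line. The counts thus do not show that expression is confined to single lines. Hs700T had 382 calls, BxPC-3 219, MIA PaCa-2 215, PANC-1 159, PATU 8988S 148, DAN G 136 and YAP-C 132, while Panc10.05 had 12. The median was 66 per line. MIA PaCa-2 had 63 lower calls, the most of the 29 lines. In 264 of the higher calls, the gene was not well above background in any of the other 28 lines. With arrays scaled to equal spread there were 5360 calls, 4124 higher and 1236 lower, so that the share of higher calls was 76.9% in place of 91.2%. The ranking of lines changed too: PSN-1 had 1271 calls in place of 27, HUPT4 1087 in place of 23, Hs766T 404 in place of 65 and Panc03.27 386 in place of 13, while Hs700T fell to 244 and MIA PaCa-2 to 87. With slide as a fixed block, Hs700T still had the most calls, while DAN G, MIA PaCa-2 and BxPC-3 had fewer and HPAC more. The difference in this fit is that from the other lines of the same slide only. DAN G and HPAC shared a slide with no other line, so their 50 calls each are the same contrast with opposite sign. A call lost in this fit does not by itself show a batch effect. CF PAC-1 could not be fitted this way. The p-values assume that a single array varies like the others. Arrays with a wider spread of ratios had more calls (r = 0.69, rho = 0.71, n = 29, permutation p = 2e-05 and 6e-05, r = 0.65 without MIA PaCa-2 and HUPT4, 0.81 within slides). Calls and spread come from the same ratios, and a gene far from the other lines raises both. A positive r was thus to be expected, and it does not test whether arrays vary alike.

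**Figure D3:**
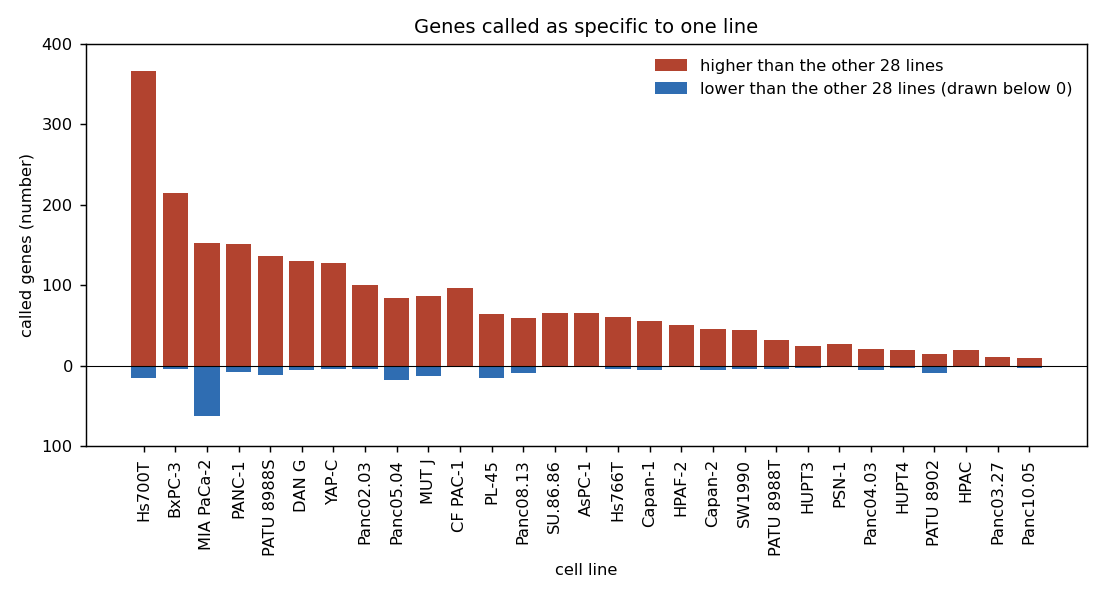
Number of genes called by limma in each line, higher than the other 28 lines (upward bars) or lower (downward bars, sizes as positive numbers). Hs700T has 366 higher and 16 lower calls, and Panc10.05 has 9 and 3.

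For each line, the called gene with the largest difference above the other 28 lines is given here. IGFBP1, an insulin-like growth factor binding protein made by liver, was 9.10 higher in AsPC-1 (standard error 1.82, limma adjusted p = 0.00983). PSCA, a surface antigen of prostate, bladder and stomach, was 9.08 higher in HPAC (standard error 1.80, adjusted p = 0.00881). CHGB, a granule protein of neuroendocrine cells, was 9.06 higher in Hs700T (standard error 1.43, adjusted p = 0.00046). Part of these differences lay in the pool channel: the Cy3 signal was 2233 for IGFBP1, 2355 for PSCA and 1482 for CHGB on these arrays, against medians of 6862, 18606 and 2462.5 on the other mix B arrays. The interleukin 13 decoy receptor IL13RA2 was 7.87 higher in Hs766T, the mucin-like MUCL3 7.82 in Panc05.04, the cancer-testis antigen XAGE1 7.44 in MUT J, and OLFM4, a marker of intestinal stem cells, 7.43 in Capan-1. The thrombin receptor family member F2RL2 was 7.20 higher in MIA PaCa-2, TFF3 6.74 in YAP-C, the serine protease HTRA3 6.69 in PSN-1 and KRTAP1-5 6.42 in Panc04.03. SUN3 (6.28) stood out in PATU 8988T, the peptide hormone APLN (6.16) in DAN G, SPANXB1 (6.08) in SU.86.86, the fatty acid binding protein FABP1 (6.01) in PATU 8988S and SERPINB3 (5.77) in BxPC-3. Collagen COL11A1 (5.64) led in PANC-1, TDRD12 (5.57) in Panc02.03, the steroid enzyme HSD11B1 (5.49) in Panc03.27, the lymphoid receptor S1PR4 (5.43) in PATU 8902, DEFB4A (5.19) in SW1990 and the iron oxidase HEPH (5.05) in HPAF-2. SUCNR1 (4.61) led in CF PAC-1, ADAM18 (4.53) in HUPT3, endothelin EDN2 (4.13) in Capan-2, RLBP1 (3.90) in Panc08.13, BCL2L11 (3.73) in PL-45 and the haemoglobin chain HBB (2.58) in Panc10.05. ARHGAP23 in HUPT4 had the largest difference of all (10.36), but its ratio on that array was 9.62 after local background correction and 0.74 in Agilent's own ratio, where the gene was not called. Some leading genes were also high in another line: TFF3 stood at 3.07 in PSN-1 against 3.53 in YAP-C. SUCNR1 stood at 2.82 in PSN-1 against 3.63 in CF PAC-1, and HEPH at 3.31 in PATU 8988S against 4.93 in HPAF-2. Some of the leading calls depended on the processing. TFF3 in YAP-C stayed called in only 4 of 13 alternatives (limma adjusted p up to 0.883), SUCNR1 in CF PAC-1 in 7 of 11, SERPINB3 in BxPC-3 in 8 of 13, F2RL2 in MIA PaCa-2 and SUN3 in PATU 8988T in 9 of 13 each and OLFM4 in Capan-1 in 9 of 12. The differences themselves stayed large, from 5.77 to 7.29 for TFF3 and from 6.18 to 7.17 for SUN3, so for these genes it was the p-value that moved.

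The 5 largest calls in the lower direction were in 4 lines. LRATD2 was at least 92.9-fold lower in MIA PaCa-2, where it was not well above background (difference -6.84, standard error 1.33, limma adjusted p = 0.00732). The potassium channel KCNK1 (-6.68) was also lower in MIA PaCa-2, but PANC-1 was close to it (-6.34 against -6.95 in MIA PaCa-2). The chromatin protein HMGA2 was lower in Hs700T (-6.39), and the kinase MAP2K4 was at least 42.0-fold lower in PATU 8988S. It was not well above background there or in PATU 8988T, and this call held in only 7 of 13 alternatives, that of KCNK1 in 9, HMGA2 in 10, LRATD2 in 11 and LGR4 in 12 of 13. Over the alternatives the differences ran from -6.92 to -4.51 for MAP2K4, -6.99 to -4.47 for KCNK1 and -7.16 to -4.44 for HMGA2. For LRATD2 they ran from -7.30 to -4.17, and for LGR4 from -7.16 to -3.21. LGR4, a receptor for R-spondins, was lower in Capan-2 (-6.09), though a second probe for it followed the first at r = 0.29 only. HMGA2 and LGR4 counted as above background in these lines, but any probe of a gene suffices for that. The line signal (log2) of the probe used was 6.15 for HMGA2 and 6.67 for LGR4. It was 6.94 for LRATD2 and 6.61 for MAP2K4, so the HMGA2 and LGR4 differences may also rest on signals at background. With slide as a block, 15 of the 28 leading higher genes that could be fitted kept an adjusted p under 0.05, and their differences from the lines on the same slide ran from 2.79 to 10.93. CF PAC-1 was alone on its slide.

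Members of the 25 lists accounted for 72 calls of 71 genes, 68 higher and 4 lower, and 40 of the 70 with a value kept an adjusted p under 0.05 with slide as a block. Cancer-testis antigens had 9 calls, all higher (11 when adjusted over the list alone), of which 5 were in MUT J: XAGE1, CT45A1 (5.27), MAGEA4 (5.09), MAGEA10 (4.86) and CTAG2 (3.48). MAGEA9 was at least 12.2-fold higher in Hs700T. Liver and gut lipoprotein genes had 8 higher calls (12 adjusted over the list alone). FABP1, APOH (4.75) and transthyretin (TTR, at least 4.74-fold) were higher in PATU 8988S. Fibrinogen FGB (4.19) and AMBP (1.87) were higher in CF PAC-1, and alpha-fetoprotein (AFP, 4.39) in BxPC-3. Classical subtype genes had 5 higher calls (7 adjusted over the list alone), of which BTNL8 (5.59), LGALS4 (5.49) and REG4 (4.66) were in PATU 8988S. The classical list of the 62-gene set had 4 calls by both adjustments, and ATP10B was higher in both Capan-1 (3.68) and HPAF-2 (3.86), which share a slide and mix C, so with slide as a block the call ended (adjusted p = 1 in both).

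Squamous genes had 5 higher calls (6 adjusted over the list alone), among them KRT13 (4.75), CLCA2 (3.32) and the desmosome protein PKP1 (1.82) in BxPC-3 and S100A8 (5.50) in Panc02.03. The basal-like list had 3 calls by both adjustments, KRT6C (4.63) in SW1990 and SERPINB3 and SERPINB4 (5.46) in BxPC-3, whose sequences are close. Exocrine-like genes had 5 calls (8 adjusted over the list alone), with CFTR, the chloride channel of duct cells, higher in Capan-1 (3.93) and the granule protein GP2 at least 4.66-fold higher in PATU 8988S. HOX genes had 4 calls by both adjustments, HOXD10 (3.50) and HOXD11 (1.42) in DAN G, HOXD8 (2.31) in Hs700T and HOXD13 (1.63) in Panc02.03. Mucins had 3 calls (4 adjusted over the list alone): MUC15, at least 10.8-fold higher in SU.86.86, MUC17 (4.35) in AsPC-1 and MUC2 (1.05) in Panc08.13. Mesenchymal genes had 2 calls by both adjustments, with the BMP antagonist GREM1 at least 7.58-fold higher in SU.86.86 and COL5A2 (6.54) in MIA PaCa-2. Epithelial junction genes had 2 calls, both lower, CDS1 (at least 7.25-fold) in MIA PaCa-2 and MARVELD2 (-3.58) in MUT J, and the same number adjusted over the list alone. NRF2 targets had ABCC2 (5.73, Hs700T) and CBR1 (-3.71, PATU 8902), or 3 calls adjusted over the list alone. Cholesterol synthesis genes had FDFT1 (3.89, HUPT4) and CYP51A1 (-4.07, MUT J), or 1 over the list alone. Quasi-mesenchymal GPM6B (3.24, Hs700T), HLA-DQA1 (3.73, Panc02.03) and ribosomal RPS16 (4.52, PANC-1) were single calls by both adjustments. Endoderm factors, interferon response, MHC class I, proliferation and hypoxia lists had 0 calls by either adjustment with limma.

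Markers of cell types other than the cancer cells were followed as well. Endocrine islet genes had 4 calls (6 adjusted over the list alone). Hs700T had CHGB, the prohormone convertase PCSK1 (2.96) and glucagon (GCG, at least 1.96-fold), and CPE when adjusted over the list alone. NEUROD1 was at least 2.30-fold higher in HUPT4. Fibroblast genes had 6 calls (8 adjusted over the list alone): COL3A1 (6.62), COL1A2 (3.72) and COL6A3 (2.65) in MIA PaCa-2, LUM (4.62) and DCN (3.24) in AsPC-1 and FAP (3.76) in Panc02.03. Endothelial genes had 4 calls (7 adjusted over the list alone): the angiopoietin receptor TEK (4.97) and TIE1 (3.35) in Hs766T, KDR (2.29) in PSN-1 and EMCN, at least 2.96-fold, in MIA PaCa-2. Leukocyte genes had 3 calls by both adjustments, CD8A (2.84) in PATU 8988T, CD14 (2.23) in HPAF-2 and CD79A (2.04) in Panc04.03. The T cell gene CD2 and the B cell gene MS4A1 were above background in 1 line each. Beside the fibroblast calls, COL1A1 ranged little (SD 0.58) and was called in no line. PECAM1, a further endothelial gene, was called in no line by either adjustment, while VWF and CDH5 in DAN G and ROBO4 in Hs766T were called only when adjusted over the list alone.

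PATU 8988S and PATU 8988T, whose names share a number, were compared as 2 arrays with no replicate and no test. They differed at least 4-fold in 1368 of 25999 genes, 681 higher in PATU 8988S and 687 in PATU 8988T. Over all 406 pairs of lines, the median was 1251 genes (274 to 2585), and 242 pairs differed in fewer. The 32 pairs on a common slide, as these are, had a median of 1200. Among genes higher in PATU 8988S, TSPAN8 (8.57), AGR2 (8.55), the endoderm factor FOXA2 (8.07) and the amino acid decarboxylase DDC (7.99) differed most. PRR15L was at least 202-fold and ANXA10 at least 122-fold higher, and MAL2 (7.44), AKR1B10 (6.75), the microvillus protein VIL1 (6.65) and lysozyme (LYZ, 6.52) followed. PATU 8988T had more of RFLNB (at least 319-fold), SUN3 (at least 302-fold), CMTM3 (difference -8.0), the pentraxin PTX3 (at least 175-fold), BNIP3 (at least 121-fold), TTC7B (-6.86), LHFPL6 (-6.35), the adenylate kinase AK4 (-6.27), MARCHF4 (at least 68.4-fold) and FSTL1 (-5.99).

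The classical subtype list had a median difference of 5.26 in favour of PATU 8988S, with 22 of 25 genes at least 4-fold higher and a median above all 10000 random lists of equal size and signal (percentile 100). Its counterpart in the 62-gene set had a median of 3.96 (14 of 20 genes, percentile 100). Epithelial junction genes had a median of 2.89 (14 of 23 genes, percentile 100), with CDH1 at 6.28 and EPCAM at 5.35. Endoderm factors had 1.88 (9 of 18 genes, percentile 100), proliferation genes 1.28 (4 of 26 genes, percentile 100, TOP2A 2.82), cholesterol synthesis genes 1.1 (1 of 20 genes, percentile 100) and exocrine-like genes 1.1 (4 of 15 genes, percentile 100). NRF2 targets lay at 0.41 (percentile 97.1), ribosomal proteins at 0.16 (percentile 98.4) and liver and gut lipoproteins at 0.14 (percentile 96.0). In the other direction, mesenchymal genes had a median of -1.35 (8 of 22 genes at least 4-fold higher in PATU 8988T, percentile 0), with LOXL2 at -5.46, AXL at -5.31 and VIM at -4.98. MHC class I genes lay at -0.86 (percentile 0.08), interferon response genes at -0.65 (percentile 0.11) and quasi-mesenchymal genes at -0.60 (percentile 0.26). Cancer-testis antigens had a median of -0.46 (percentile 0.21), which turned to 0.09 on Agilent's own ratios and 0.06 with arrays scaled to equal spread. Endocrine islet (-0.30), MHC class II (-0.49), hypoxia (-0.35), HOX (-0.23), squamous (-0.29), fibroblast (-0.36), basal-like (-0.10), leukocyte (0.06) and mucin (0.02) lists had medians between percentiles 1.05 and 72.1. Many probes of some lists were at background: 13 of 23 cancer-testis, 10 of 17 islet and 4 of 9 endothelial genes were above it in neither line. With genes above background in 1 line only at their bound and those in neither at 0, the medians of the cancer-testis, islet, endothelial, HOX, squamous, fibroblast and leukocyte lists were 0, that of quasi-mesenchymal genes -0.37 and that of mesenchymal genes -1.17. The endothelial median of -0.72 thus rests on probes at background. These percentiles describe the 2 arrays only.

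**Figure D4:**
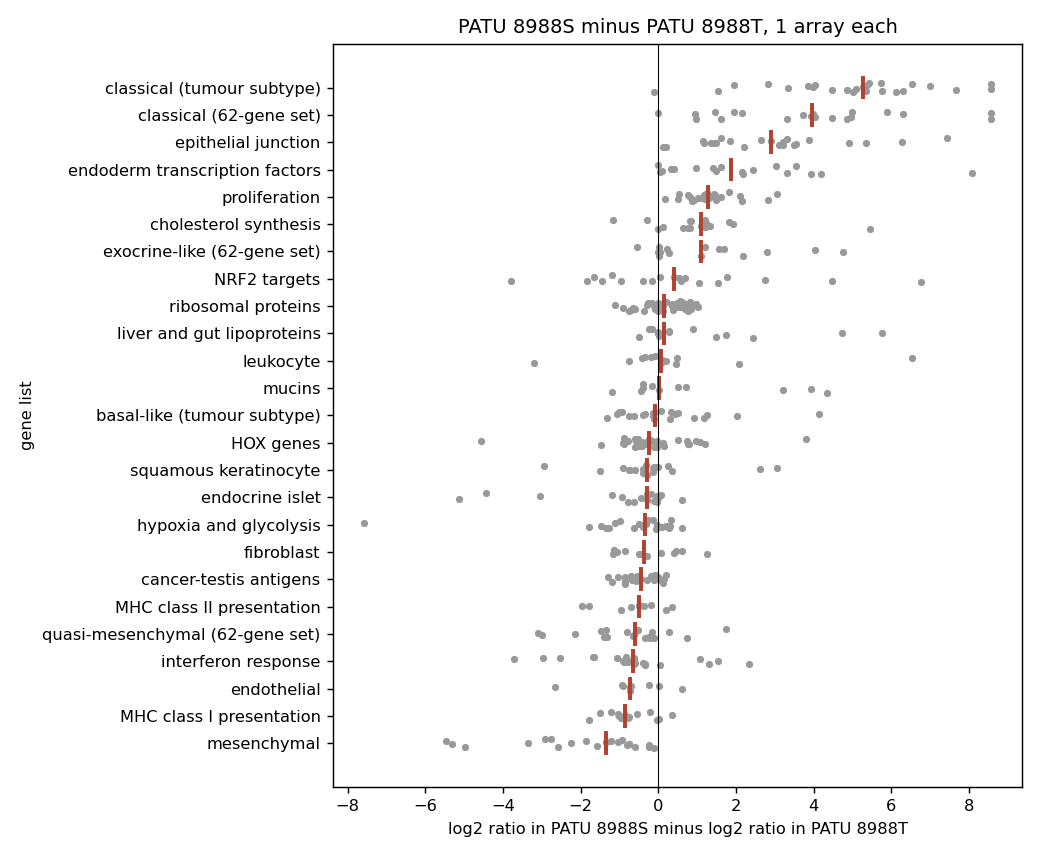
Difference of log2 ratios, PATU 8988S minus PATU 8988T (horizontal), for each gene (grey points) of 25 lists (vertical), with the list median as a red bar. Medians run from -1.35 for mesenchymal genes to 5.26 for classical subtype genes.

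Slides and reference mixes were tested as batches. Across the 9 slides with over 1 array, 30 genes differed between slides (limma, adjusted p under 0.05), and 5 when the mix C arrays were left out, against 3229 and 2713 at an unadjusted p under 0.05. The 3 mix C arrays differed from the 26 mix B arrays in 263 genes, 165 higher and 98 lower (limma, adjusted p under 0.05). This count fell to 119 on Agilent's ratios and to 60 with arrays scaled to equal spread. Their lines, slides, scanner model and software version differ as well, so these cannot be told apart. The median correlation of 2 arrays over genes was 0.15 and the lowest -0.06 (SU.86.86 and HPAC), so no pair of arrays ran opposite to another.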

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

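The counts of other splits and of orders of the slide labels were chosen only after the results were seen, as were the spike-in values, while the tests of the 2 channels behind the mix difference were written before.

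Spike-in transcripts, control RNAs added in known ratios, were not used in any comparison. The scanner files report the slope of their observed on their expected log ratios, whose median over the 29 arrays was 0.461 (range 0.36 to 0.60), where an exact measurement would give 1. The intercept had a median of -0.671 (log10) on the 26 mix B arrays and of 0.388 on the 3 mix C arrays, and the ranges did not overlap (-0.88 to -0.48 against 0.31 to 0.44). No biological explanation applies to these control values.

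The 263 genes that separated mix C from mix B arrays were more than any other split tried gave. Of 100 splits of the arrays into 3 and 26, only the real one (1 of 100) gave as many, and the highest other gave 89. The count itself fell to 119 on Agilent's ratios and to 60 with arrays scaled to equal spread, and the splits were not repeated under these settings. Only part of all possible splits was drawn. The draw did not keep arrays of a slide together, while Capan-1 and HPAF-2 share a slide. Chance is thus unlikely for the processing used here, but not excluded. Over the 263 genes, the line channel (Cy5) accounted for a median of 71.2% of the ratio difference and the pool channel (Cy3) for 28.8%. The first value is what a difference between the 3 lines and the other 26 would give. A contribution of the pools stays open, because 28.8% lies between the bounds set beforehand, and lines, slides, scanner and software change together with the mix. Between slides 30 genes differed, more than in any other order tried of the slide labels (1 of 101 with the real one included, highest other 16), but these orders crossed the mixes, and 1 slide holds mix C alone, so this excess can be the mix difference. Within the mix B arrays 5 genes differed, and 4 of 101 orders with the real one included gave as many (highest other 12), so the excess over chance there is slight. No biological explanation was tested, because lines are not grouped.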

How the results depend on the processing

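The alternatives were fixed before the data were examined, except the count of calls also made on Agilent's ratios (1774), chosen only after the result was seen. Of 594 repeats of the correlations 27 changed sign and 13 no longer passed, and of 447 repeats of single calls 60 no longer passed. Of 208 repeats of the PATU 8988 list medians, 3 changed sign, 80 others were counted as moved and 125 as the same. How far such a median moves by technical noise alone was not measured. With slide as a fixed block 17 of 33 single calls no longer passed. As each line was then set only against the others of its slide, this does not by itself show a batch effect.

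The 2560 line-specific calls became 5360 with arrays scaled to equal spread, 1689 with median centring, 1627 with the filter on 3 arrays and 1369 at a difference of 2 or more. The 30 genes differing between slides became 58 on Agilent's ratios and 58 on the authors' table, 18 with an offset of 10, 19 with median centring, 18 with the filter on 3 arrays and 5 without the mix C arrays. The 263 mix genes became 119 on Agilent's ratios and 119 on the authors' table, 60 with scaling and 174 with the filter on 3 arrays. Between PATU 8988S and PATU 8988T, 4989 genes differed at least 2-fold, and the cancer-testis median turned to 0.0901 on Agilent's ratios, 0.11 on the authors' table and 0.0637 with scaling.

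In the 6 lines low in junction genes, r of junction and mesenchymal scores (0.33) was -0.35 on Agilent's ratios, -0.35 on the authors' table, -0.0856 with median centring and -0.76 with scaling. Junction and classical scores (0.91) gave 0.90 with genes scaled to SD 1, 0.79 with median scores, 0.63 on Agilent's ratios, 0.63 on the authors' table, 0.70 with median centring and -0.32 with scaling. Without the mix C arrays, none of which is among the 6, r was 0.91 and no longer passed, as the other p-values in the adjustment changed. ZEB1 and junction (-0.73) gave 0.13, 0.13 and 0.98 on Agilent's ratios, the authors' table and with scaling. In the 23 other lines ZEB1 and junction (-0.53) gave -0.44 with median scores, -0.42 with scaling, -0.50 without the mix C arrays and -0.46 with slide as a block.

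Classical and quasi-mesenchymal scores (0.03) gave -0.0848 with genes scaled to SD 1, -0.00949 with median scores, -0.0776 on Agilent's ratios, -0.0776 on the authors' table, -0.00136 with an offset of 10, -0.12 with slide as a block and -0.0551 to 0.24 leaving out lines in turn. GATA6 and basal-like (0.52) gave 0.42 on Agilent's ratios, 0.42 on the authors' table and 0.0729 with scaling. Hypoxia and cholesterol (-0.08) gave 0.0504 with genes scaled to SD 1, 0.16 with median scores, 0.19 with median centring and 0.14 with slide as a block. NRF2 and proliferation (-0.23) gave 0.14 with median centring and 0.21 with scaling, and MTAP and CDKN2A in 15 lines (0.29) gave -0.00154 with scaling. The cause of these changes was not tested, except that fewer genes are tested with the filter on 3 arrays and fewer lines without mix C. The lists among the most variable genes numbered 13 to 16 under all settings. Signal over background limits dim genes: 58.7% to 67.3% of probes per array passed.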

Other observations

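The tests of the pool limit, of compression and of Cy5 light or competition at bright spots were chosen only after the results were seen, as were the genes and lists singled out here, while those of saturation and of array-wide labelling were written before.

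Some gene lists ranked the lines in ways not yet described. These rankings were not tested. MHC class II genes scored highest in CF PAC-1 (2.43), followed by Capan-2 (2.08), though the call in this list was HLA-DQA1 in Panc02.03. NRF2 targets scored highest in Hs700T (1.47) and Panc04.03 (1.31), and AKR1C3 was highest in the latter (2.36). Mucins scored highest in HPAF-2 (1.28) and HPAC (0.97). With arrays scaled to equal spread, Panc04.03 came before Hs700T, HPAC before HPAF-2 and PATU 8902 between CF PAC-1 and Capan-2. Cancer-testis antigens scored high in MUT J (2.64), Hs700T (2.2) and DAN G (1.35), and endothelial genes in Hs766T (2.24), DAN G (1.66) and PSN-1 (0.84). Both orders held under each of the 8 other normalizations and filters. MAGEA1 (4.07) and PRAME (3.55) were highest in MUT J, and ROBO4 (2.59) in Hs766T. The islet genes SCG5 (3.64) and PAX6 (2.12) were highest in Panc04.03. Among ribosomal proteins, RPS16 stood at 4.18 in PANC-1, RPL37 at 2.84 in HPAC and RPS6 at 2.77 in HUPT4, while the median SD of the list was 0.53.

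Ratios above the pool stopped near 30-fold. Of 754047 values, 17 (0.00225%) lay above log2 of 30 (4.91), and the highest value per line had a median of 4.51. A candidate explanation, formed from these values, is arithmetic: a line that makes up 1 part in 30 of its own reference cannot exceed it by more than 30-fold. This stays open, because it was formed from the same values and would allow no ratio above the limit, where 17 were found. Scanner saturation would need most bright spots to be saturated, but only 3 spots (2.80%) of those at a log2 ratio of 4 or more were. A limit of the measurement alike in both directions would also stop ratios below the pool. However, 481 ratios lay as far below it, and the lowest value per line had a median of -6.79, which argues against such a limit. Milder compression of all ratios stays open, because a pool can far exceed a line that lacks a gene. The spike-in slopes of 0.36 to 0.60 are what compression would give, though the correlation of observed with expected log ratios was as low as 0.58. Of the values above the limit, ARHGAP23 in HUPT4 (9.62) had 0.74 in Agilent's ratio, while PSCA in HPAC (5.93 and 6.09), CHGB in Hs700T (5.62 and 5.70) and IGFBP1 in AsPC-1 (5.44 and 5.47) were alike in both. No biological explanation was tested.

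The pool signal, which should be the same on each mix B array, was not constant where a line was brightest. Over 2133 higher calls on mix B arrays, the Cy3 signal differed from the same probe on the other arrays by a median of 0.225 (log2) among the 533 calls brightest in Cy5 and of 0.01 among the 534 dimmest, a gap of 0.218. Light of the Cy5 dye reaching the Cy3 channel may account for such a rise, and would make these ratios too small. Competition for the probe would lower the Cy3 signal instead, against the 0.225 found. At Cy5 signals of 100000 or more, however, the median was -0.198 (50 of 78 calls lower), so competition at these spots stays open: for PSCA in HPAC the Cy3 signal was 2355 against a median of 18606 on the other mix B arrays. Whether labelling of whole arrays contributed stays open too, because each array was centred on its own median (dimmest minus brightest -0.218). No biological explanation was tested.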
